A study of Mus musculus with 14 samples.

How the data were processed

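RNA of the plantaris muscle of 25-month-old male C57BL/6J mice was hybridised to 14 Affymetrix Mouse Gene 1.0 ST arrays, 2 for each of days 0, 1, 3, 5, 7, 10 and 14 of overload by synergist ablation. On each day one array held a pool of left and the other a pool of right muscles of 6 animals, and the design text was read as taking both pools from the same animals. Day and animals therefore cannot be separated. The labels give the RNA input as 100 ng in the design text and 250 ng in the labelling protocol, and which applied is not known. The deposited values are log2 signals per probe set, normalized between arrays by the submitters; the method of normalization is not given in the sources used here, and Partek is named in their processing notes without a version. The unit was checked on the values, which lay between 2.35 and 14.8. Scanner files were not used here, so no background or detection call stands behind a value, and the number of arrays limits the precision.

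Of 35557 probe sets, the annotation paired 21789 with 1 gene symbol, 1621 with several and 12147 with none. Only the first kind was tested. Where a gene had more than 1 probe set (999 genes), the one with the highest mean over the 14 arrays stood for it, which left 19938 genes. No filter on low values was applied. No coordinates are given, since the genome build of the annotation is not stated.

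Linear models were fitted to all 14 arrays with limma 3.58.1 in R 4.3.3, with the day as group and moderated variances (7 residual degrees of freedom, prior 4.95, median standard error of a difference 0.097). Each day was compared with day 0 and with the sampled day before it, a moderated F test covered all days, and right was compared with left with the day as a block. P values are two-sided, adjusted by Benjamini and Hochberg over all genes, and called under 0.05. Of 43 gene lists fixed before the data were examined, the 42 with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over all 252 list and day tests; camera with an estimated correlation and fry were alternatives. The list of red blood cells had 4 measured members and was not tested. The median, mean and test of a list differed in sign in 25 of the 252 tests and in 0 of the 153 called.

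Genes were named by a rule fixed before the data were examined. For each day these were the 12 largest rises and 8 largest falls against day 0, among called genes with both arrays of the day beyond both of day 0. Predicted genes, microRNA and small nucleolar RNA genes were left out. To these were added the 3 members of each list with the largest called change on any day, the 3 largest rises and falls between successive days, and 24 genes fixed by name. Genes named outside the rule are Ngp, Camp, Zdbf2 and Peg10, chosen after their values were seen, and the 3 with the smallest p between sides, Tspan8, Igfbp6 and Adamts9.

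Alternatives were quantile normalization, equal array medians, the 25% of genes with the lowest signal left out, all probe sets, the mean of a gene's probe sets, an intensity trend with robust estimation, array weights, the side as a block, only the 4 arrays compared, stricter thresholds and each array left out in turn. An array shift that sets the median difference from day 0 to 0, and counts without bone marrow, B cell, red blood cell and keratinocyte genes, were added after the data were seen. The choices, the 43 gene lists and the other alternatives were fixed before the data were examined. The lists of granule genes of granulocyte precursors and of imprinted genes were written after the data were seen. The set of genes made only by muscle fibres was chosen after the data were examined but before its own values were seen. Right minus left differences correlated between days across genes at r from -0.19 to 0.35, with a median of 0.07 and 6 of 21 pairs of days over 0.1. Days 5, 7 and 10 shared part of their side difference (r = 0.354, 0.264 and 0.186). The side entered the comparisons between days as a block only in an alternative, as planned.

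The procedure was tested on simulated data with known changes. On day 3 it recovered 2% of 50 genes changed by 0.25 on the log2 scale, 62% of 50 changed by 0.5, 98% of 50 changed by 1 and 100% of 50 changed by 2. It called 8 unchanged genes on that day and 0 on the 5 other days. For sides it recovered 93 of 100 changed genes and called 5 unchanged ones, and among lists it called the changed one and 0 of 251 other tests. The noise was drawn independently for each gene, so the list result does not show how often lists of correlated genes are called wrongly.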

Results

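Gene expression was measured in the plantaris, a calf muscle of the hindlimb, of 25-month-old male C57BL/6J mice. The plantaris had been overloaded by synergist ablation, in which the gastrocnemius and soleus are removed so that the plantaris takes over their load and grows. The series title names the effect of age on the muscle transcriptome during hypertrophy as its subject. The comparisons here are between days of overload in old mice, and young muscle was not analysed here. No array is labelled as coming from sham-operated animals. Effects of the surgery and of the added load therefore cannot be told apart in any comparison with day 0. RNA was taken on days 0, 1, 3, 5, 7, 10 and 14, with 2 Affymetrix Mouse Gene 1.0 ST arrays per day. One array of each day held a pool of left and the other a pool of right plantaris muscles from 6 animals. The values were log2 signals with array medians between 7.91 and 7.97 over all probe sets. Over the 19938 genes tested the array medians lay between 8.25 and 8.42. The left and right arrays of a day correlated at r between 0.994 and 0.997 across genes, and genes are not independent replicates. Both pools of a day were read as coming from the same animals, so the p-values measure the spread between sides and arrays. Each day is a different set of animals. Differences are log2 differences from day 0 with their standard error, from limma with n = 2 arrays per day, and the number of arrays limits their precision. Adjusted p values are from limma for genes and from its camera test for gene lists.

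On day 1 chemokine and cytokine genes were among the 12 largest rises. The chemokine genes Ccl3, Cxcl2, Ccl2 and Cxcl3 rose by 5.44 ± 0.23, 5.37 ± 0.28, 4.81 ± 0.13 and 4.71 ± 0.15 on the log2 scale. Ccl3 was thus 43.4-fold above day 0 (adjusted p = 4.5e-09). The cytokine genes Il6 and Il1b rose by 4.75 ± 0.25 and 4.49 ± 0.18. Arg1, which encodes arginase 1, rose by 5.02 ± 0.15. Ptgs2, which encodes the inducible cyclooxygenase, rose by 4.58 ± 0.23, and Timp1, an inhibitor of matrix metalloproteinases, by 4.38 ± 0.13. Acod1, the enzyme that makes itaconate in myeloid cells, rose by 4.44 ± 0.28, the myeloid receptor gene Clec4e by 4.44 ± 0.25 and Slfn4 by 4.53 ± 0.17. Of the 26 cytokine and chemokine genes, 24 rose (24 adjusted over the list alone) and 1 fell, with a median of 2.03 (adjusted p = 4.5e-14, and adjusted p = 0.206 with an estimated correlation). Of 15 neutrophil genes 13 rose (13 adjusted over the list alone), with a list median of 1.85 (adjusted p = 1.2e-05, and adjusted p = 0.375 with an estimated correlation). Trem1 rose by 4.24 ± 0.12 and Il1r2 by 4.09 ± 0.16. Both genes of granulocyte precursors in that list, Ngp and Camp, stood at -1.52 and -1.14 on day 1 (adjusted p = 0.0798 and 0.0041).

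Early response genes rose on the same day. The transcription factor gene Myc rose by 3.33 ± 0.10, a 10.0-fold increase, and the immediate-early genes Atf3, Ier3 and Egr1 rose by 2.56 ± 0.19, 2.46 ± 0.15 and 2.30 ± 0.11. In that list 11 of 13 members rose (11 adjusted over the list alone), with a median of 1.505 (adjusted p = 5.9e-07, and adjusted p = 0.23 with an estimated correlation). Ankrd1, a stretch-responsive ankyrin repeat protein of muscle, rose by 3.40 ± 0.20, and Xirp1, which binds actin at sites of muscle damage, by 2.02 ± 0.19. Of 14 stretch and sarcomere stress genes 10 rose (11 adjusted over the list alone) and the median was 1.03 (adjusted p = 3.4e-04, and adjusted p = 0.398 with an estimated correlation). The metallothionein gene Mt1 and the antioxidant gene Srxn1 rose by 3.20 ± 0.11 and 2.86 ± 0.07, and 8 of 11 genes of oxidative stress and metallothioneins rose (8 adjusted over the list alone, median 1.36, adjusted p = 2.0e-04, and adjusted p = 0.23 with an estimated correlation). Slc2a1, the glucose transporter GLUT1, rose by 2.75 ± 0.08 and Adm, which encodes adrenomedullin, by 2.33 ± 0.09. Both belong to the hypoxia list, of which 7 of 10 rose and 1 fell (7 rose adjusted over the list alone, median 0.66, adjusted p = 0.0079, and adjusted p = 0.316 with an estimated correlation).

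The largest fall on day 1 by the naming rule was that of Ddit4l, an inhibitor of mTORC1 signalling, which fell by 3.40 ± 0.13 on the log2 scale, which is 10.5-fold. Ky, a muscle Z-disc protein, fell by 3.25 ± 0.13. Stxbp4 fell by 3.09 ± 0.21, Lrrc30 fell by 3.03 ± 0.13, the phospholipase C gene Plcd4 fell by 2.93 ± 0.13 and the methyltransferase gene Inmt fell by 3.01 ± 0.16. Alb, which encodes serum albumin, fell by 3.03 ± 0.18. Adipocyte genes were lower on day 1, with 13 of 15 falling (13 adjusted over the list alone) and a median of -0.55 (adjusted p = 3.4e-05, and adjusted p = 0.316 with an estimated correlation). Vessel wall genes were lower as well: 11 of 13 smooth muscle and pericyte genes fell (12 adjusted over the list alone), with Myh11, the smooth muscle myosin, at -1.42 ± 0.13 (list median -0.70, adjusted p = 2.9e-05, and adjusted p = 0.316 with an estimated correlation). Of 16 endothelial genes 8 fell (8 adjusted over the list alone) and 2 rose, with the vascular growth factor receptor gene Kdr at -1.24 ± 0.07 and Rgcc at 1.99 ± 0.16 (list median -0.26, adjusted p = 0.0213, and adjusted p = 0.493 with an estimated correlation). The endothelial call ended without the right pool of day 1 and with the 25% of genes with the lowest signal left out. Over all genes 4455 were higher and 4504 lower on day 1 than on day 0, and 980 and 630 of these differed by at least 2-fold.

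By day 3 macrophage genes stood at their highest median of the 6 sampled days. All 22 macrophage and monocyte genes rose (22 adjusted over the list alone), with a median of 2.78 (adjusted p = 3.7e-17, and adjusted p = 0.23 with an estimated correlation). Examples are the scavenger receptor gene Msr1 at 3.81 ± 0.13 and Ctss, the lysosomal protease cathepsin S, at 3.78 ± 0.12; Ms4a7 reached 4.33 ± 0.14 on day 5. Ms4a6d and Ms4a4a, from the same membrane protein family, rose by 4.69 ± 0.12 and 4.07 ± 0.15 on day 3, the pattern receptor gene Tlr13 by 4.23 ± 0.20 and Hmox1, the heme oxygenase of heme breakdown, by 4.04 ± 0.13. Timp1 (5.35 ± 0.13), Arg1 (5.03 ± 0.15), Ccl3 (4.59 ± 0.23), Ccl2 (4.54 ± 0.13) and the chemokine gene Ccl7 (4.05 ± 0.17) were also among the 12 largest rises. Cell division genes, of which 5 of 33 had risen and 5 had fallen on day 1, all rose on day 3 (33 adjusted over the list alone, median 1.78, adjusted p = 9.1e-16, and adjusted p = 0.316 with an estimated correlation). Ccna2, which encodes cyclin A2, was 3.25 ± 0.28 higher on day 3 than on day 1 (adjusted p = 3.3e-06). Its log2 signal on day 0 was 8.86 on the left and 7.77 on the right array. The median of the cell cycle genes was 2.10 on day 5, with the mitotic genes Bub1 at 3.06 ± 0.28 and Prc1 at 2.93 ± 0.21, and 0.60 on day 14.

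Extracellular matrix genes rose with them. All 29 measured genes of matrix production rose on each of days 3, 5, 7, 10 and 14 (29 adjusted over the list alone), with medians of 2.01, 2.62, 2.80, 2.66 and 2.62 (day 14, adjusted p = 8.7e-26, and adjusted p = 0.23 with an estimated correlation). Lox, the enzyme that crosslinks collagen, rose by 4.03 ± 0.17 on day 3, and Postn, which encodes the matrix protein periostin, by 4.25 ± 0.19 on day 10. The Wnt-binding protein gene Sfrp2 was 4.20 ± 0.22 higher on day 3 than on day 1, and stayed within 4.53 to 4.68 above day 0 on days 5 to 14. The falls of day 3 were led by Gdap1, a protein of the outer mitochondrial membrane, which fell by 3.88 ± 0.10 on the log2 scale (14.8-fold). Odf3l2 fell by 3.63 ± 0.11, the kinase gene Mylk4 fell by 3.50 ± 0.17, the resistin-like gene Retnla fell by 3.49 ± 0.34 and the muscle methyltransferase gene Mettl21c fell by 3.40 ± 0.20. Day 3 had 4807 higher and 5310 lower genes than day 0, with 1513 and 900 of them at least 2-fold apart.

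On days 5 and 7 Timp1, the imprinted gene Mest, C1qtnf3, Cthrc1 and Sfrp2 were among the 12 largest rises. Mest rose by 4.70 ± 0.12 on day 5 and 5.17 ± 0.12 on day 7, C1qtnf3 by 4.32 ± 0.11 and 5.22 ± 0.11, and Cthrc1 by 4.45 ± 0.12 and 4.68 ± 0.12. P4ha3, a subunit of the collagen prolyl hydroxylase, rose by 4.22 ± 0.08 on day 7, and Tnc, which encodes tenascin C, by 4.05 ± 0.16. Myh3, the embryonic myosin heavy chain, rose by 3.73 ± 0.16 and 4.20 ± 0.16 and was thus 18.3-fold above day 0 on day 7 (adjusted p = 1.4e-09). The lectin receptor gene Clec4n rose by 4.14 ± 0.16 on day 5. Among the falls, Ostn, the muscle secreted peptide osteocrin, fell by 4.06 ± 0.26 on day 5 and fell by 3.52 ± 0.26 on day 7. The sodium channel subunit gene Scn4b fell by 3.66 ± 0.25 and Smco1 fell by 3.65 ± 0.15 on day 5, and Slc15a5 fell by 3.27 ± 0.11. Timp4 fell by 3.36 ± 0.11 on day 7, against the rise of Timp1 by 4.82 ± 0.13. There were 5257 genes higher and 6724 lower on day 5 and 5302 and 7243 on day 7, of which 1753, 1009, 1709 and 846 were at least 2-fold apart.

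Days 10 and 14 kept the matrix and developmental genes high, while the chemokine genes Ccl3, Cxcl2, Ccl2 and Cxcl3 stood below their day 1 values. Ccl8 went the other way, from 1.10 on day 1 to 3.65 on day 10. C1qtnf3 stood at 5.49 ± 0.11 and 5.35 ± 0.11, Mest at 5.35 ± 0.12 and 4.97 ± 0.12, and Cthrc1 at 4.87 ± 0.12 and 4.55 ± 0.12 on the 2 days. Plagl1, a zinc finger gene that is imprinted, rose by 4.48 ± 0.15 and 4.27 ± 0.15, the long noncoding RNA gene Meg3 by 3.73 ± 0.10 on day 14 and Lrrc15 by 4.14 ± 0.14 on day 10. The cytokine and chemokine list had a median of 0.54 on day 14, when 15 of 26 members still rose (15 adjusted over the list alone, adjusted p = 1.6e-04, and adjusted p = 0.316 with an estimated correlation), Ccl8 by 3.58 ± 0.21. Arg1 was 0.11 ± 0.15 above day 0 by then (adjusted p = 0.561). Among the falls of day 14 were Odf3l2 at -3.24 ± 0.11, Neto2 at -3.18 ± 0.15, Gdap1 at -3.12 ± 0.10 and Asb4 at -2.65 ± 0.11. Alb stood at -3.12 ± 0.18 and Inmt at -2.72 ± 0.16, both also among the falls of day 1. There were 5154 genes higher and 6842 lower on day 10 and 4559 and 6074 on day 14, of which 1614, 781, 1209 and 430 were at least 2-fold apart. Without the right pool of day 14, 4028 genes were lower on day 14.

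**Figure D1:**
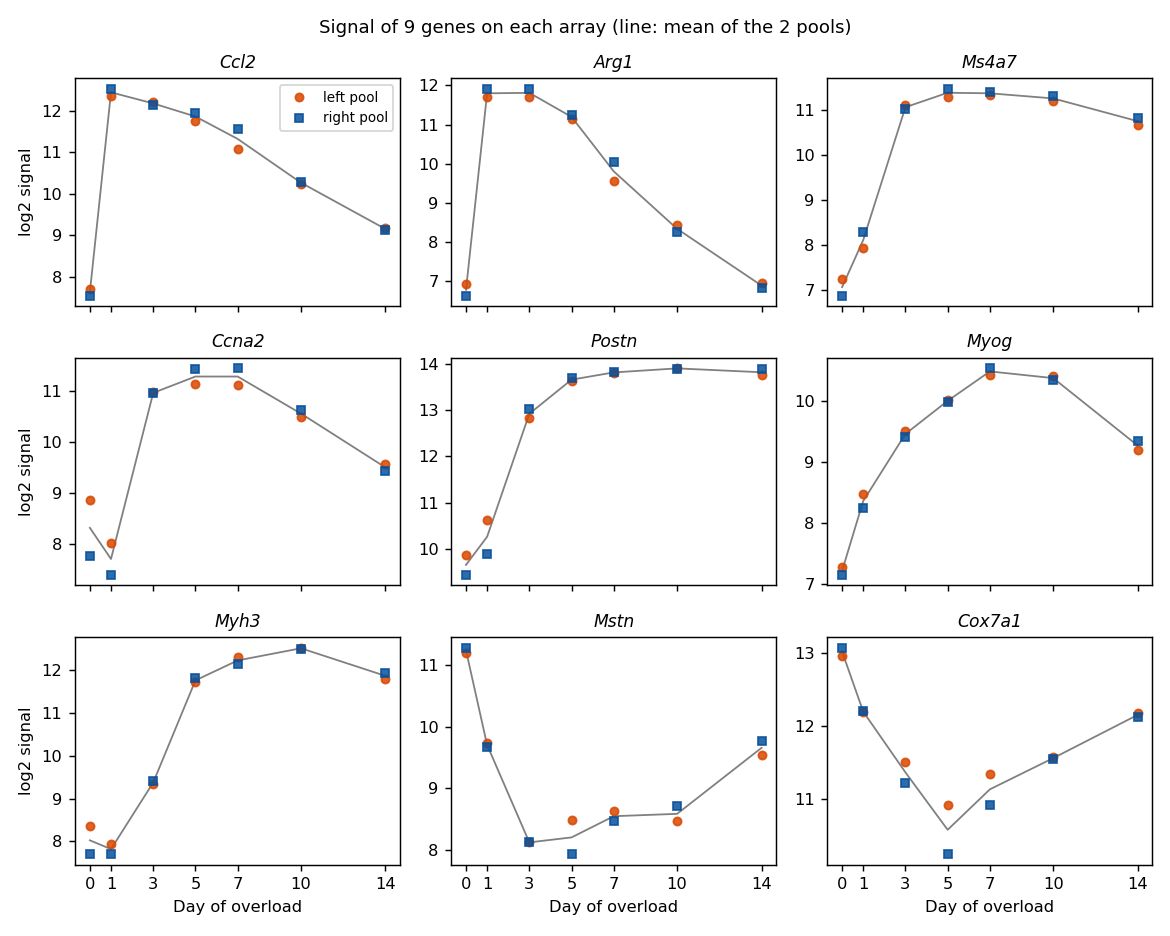
Log2 signal (vertical axis) of 9 genes on each array against the day of overload (horizontal axis); circles are left pools, squares right pools and the line joins the means of the 2 pools of a day. Ccl2 and Arg1 were highest on days 1 and 3, Ccna2 on days 5 and 7 and Myh3 on day 10, whereas Mstn was lowest on day 3 and Cox7a1 on day 5.

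Genes of ribosome biogenesis had their highest median on day 1 and those of ribosomal proteins on day 7. Of 31 genes of ribosome biogenesis and RNA polymerase I, 25 rose on day 1 (25 adjusted over the list alone), with a median of 0.69 (adjusted p = 7.5e-09, and adjusted p = 0.316 with an estimated correlation). The nucleolar genes Nop58, Gnl3 and Ddx21 rose by 1.68 ± 0.12, 1.45 ± 0.12 and 1.23 ± 0.09, and Polr1b, a subunit of RNA polymerase I, by 0.73 ± 0.07. The median was 0.27 on day 7 and -0.10 on day 14, when the list did not pass (adjusted p = 0.374 with camera). Ubtf, which encodes the RNA polymerase I factor UBF, did not pass on any day and lay between 0.06 ± 0.08 and 0.15 ± 0.08. Rrn3, the initiation factor TIF-IA, was at -0.58 ± 0.07 on day 10 (adjusted p = 2.4e-05). Of 46 ribosomal protein genes, 40 rose on day 7 (41 adjusted over the list alone) with a median of 0.59 (adjusted p = 4.4e-11, and adjusted p = 0.316 with an estimated correlation), against 12 on day 1 (2 adjusted over the list alone). The muscle-specific paralogue Rpl3l, which is not in that list, fell by 1.07 ± 0.25 on day 1 and fell by 3.13 ± 0.25 on day 5, and stood at -1.67 ± 0.25 on day 14. Rpl3 itself was matched only to probes of several genes and was not tested. Of 23 translation factor genes 11 rose on day 1 (12 adjusted over the list alone) and 2 fell, with a median of 0.23 (adjusted p = 0.0092, and adjusted p = 0.398 with an estimated correlation). Eif1a rose by 2.35 ± 0.09 and Eif4ebp1, a repressor of cap-dependent translation, by 1.38 ± 0.08, while Eef2k, the kinase that inhibits elongation, fell by 1.43 ± 0.08.

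Most amino acid transporter genes were higher on day 5. Slc7a5, the light chain of the leucine transporter, rose by 2.42 ± 0.09 on day 1 and stood at 1.06 ± 0.09 on day 14, and Slc7a11, the cystine transporter, rose by 4.27 ± 0.24 on day 1. In that list 9 of 12 rose on day 5 (9 adjusted over the list alone) and 2 fell, with a median of 1.43 (adjusted p = 1.5e-04, and adjusted p = 0.316 with an estimated correlation). Of 22 genes of the unfolded protein response 19 rose on day 1 (19 adjusted over the list alone), with a median of 1.39 (adjusted p = 4.7e-11, and adjusted p = 0.23 with an estimated correlation). Examples are Edem1 at 2.09 ± 0.13 and, on day 3, Sdf2l1 at 2.21 ± 0.09 and Asns, the asparagine synthetase, at 2.03 ± 0.16. The median of that list was 0.37 on day 14. Proteasome genes were lower on day 10, when 17 of 31 fell (17 adjusted over the list alone) with a median of -0.29 (adjusted p = 0.0303, and adjusted p = 0.527 with an estimated correlation), a call that ended without the right pool of day 10.

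Genes of energy metabolism fell. All 36 measured genes of oxidative phosphorylation fell on days 3, 5 and 7 (36 adjusted over the list alone), with medians of -0.96, -1.06 and -0.80 (day 5, adjusted p = 1.1e-12, and adjusted p = 0.316 with an estimated correlation). Cox7a1 and Cox8b, the muscle forms of cytochrome oxidase subunits, stood at -2.45 ± 0.19 and -1.91 ± 0.13 on day 5. On day 14 the list median was -0.51, with 32 of 36 still lower. All 18 citric acid cycle genes fell on day 5 (18 adjusted over the list alone), with a median of -1.23 (adjusted p = 1.6e-08, and adjusted p = 0.316 with an estimated correlation) and with Sucla2 at -1.93 ± 0.14 and Idh3a at -1.76 ± 0.10. All 19 fatty acid oxidation genes fell on day 5 (19 adjusted over the list alone), with a median of -1.18 (adjusted p = 6.9e-09, and adjusted p = 0.316 with an estimated correlation). Acadm stood at -1.82 ± 0.10 and, on day 7, the uncoupling protein gene Ucp3 at -1.98 ± 0.17. Of 16 glycolysis and glycogen genes 15 fell on day 5 (15 adjusted over the list alone), with a median of -1.07 (adjusted p = 7.1e-05, and adjusted p = 0.379 with an estimated correlation), among them the phosphorylase kinase subunit Phkg1 at -3.08 ± 0.20 and Gpd1 at -2.74 ± 0.15. A set of 30 genes written down as made only by muscle fibres, chosen after the data were examined but before its own values were seen, had a median of -0.89 on day 5.

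Developmental contractile genes rose while adult fast-fibre genes fell. All 10 developmental genes rose on days 7, 10 and 14 (10 adjusted over the list alone), with medians of 2.53, 2.74 and 2.34 (day 10, adjusted p = 3.8e-09, and adjusted p = 0.206 with an estimated correlation). On day 10 Myh3 rose by 4.48 ± 0.16, the neonatal myosin Myh8 by 3.08 ± 0.15 and the cardiac-type troponin gene Tnnt2 by 2.99 ± 0.11. Of 14 fast-fibre genes 13 fell on day 5 (14 adjusted over the list alone), with a median of -0.83 (adjusted p = 1.0e-04, and adjusted p = 0.442 with an estimated correlation). The 30 genes written down as made only by muscle fibres had a median of -0.89 on the same day. A fall particular to fast-fibre genes was therefore not shown, and a lower share of fibre RNA cannot be told apart. Among the fast-fibre genes Ampd1, the muscle AMP deaminase, fell by 1.99 ± 0.18 on day 5 and the troponin I gene Tnni2 fell by 1.41 ± 0.16. The adult myosin genes moved less: Myh4, Myh1 and Myh2 stood at -0.66 ± 0.09, -0.61 ± 0.12 and -0.76 ± 0.13 on day 5 (adjusted p = 5.9e-05, 6.1e-04 and 3.0e-04) and at -0.35 ± 0.09, 0.11 ± 0.12 and 0.09 ± 0.13 on day 14 (adjusted p = 0.0078, 0.421 and 0.564). On day 14, 7 of 11 slow-fibre genes rose (7 adjusted over the list alone) and 2 fell, with a median of 1.03 (adjusted p = 0.0185, and adjusted p = 0.398 with an estimated correlation), a call that ended with the 25% of genes with the lowest signal left out. The slow-fibre members diverged: Tnnc1 rose by 2.50 ± 0.28 on day 10, while Myl3 and Myl2 stood at -2.63 ± 0.24 and -2.33 ± 0.32 on day 5. Myh7, the slow myosin, stood at -1.43 ± 0.37 on day 5 and 1.03 ± 0.37 on day 14 (adjusted p = 0.0327), where the day 5 call ended without the right pool of day 5 and the day 14 call without either pool of day 14 or the right pool of day 0. The day 14 call of Myh4 ended with the median difference set to 0.

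**Figure D2:**
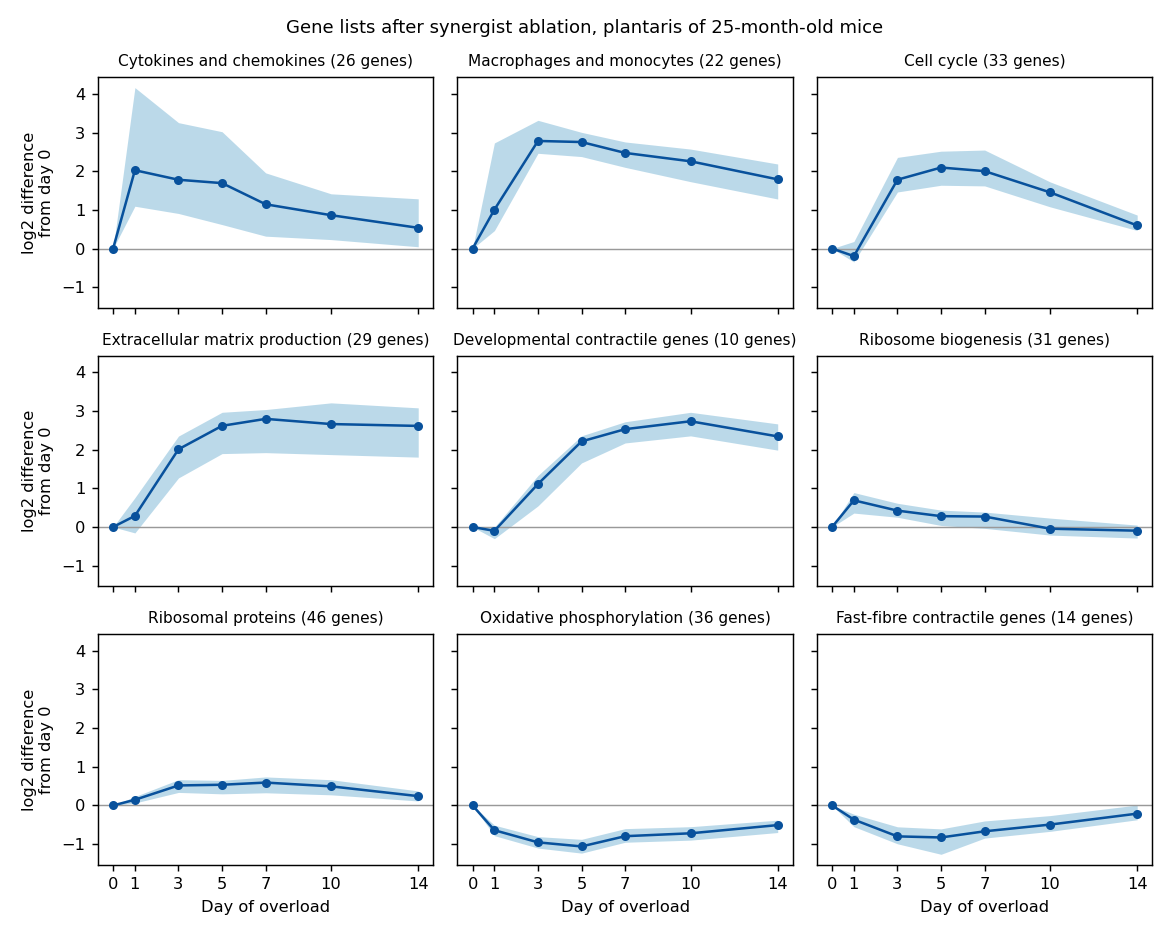
Median log2 difference from day 0 (points and line, vertical axis) and the range between the quartiles of the members (band) for 9 gene lists against the day of overload (horizontal axis). Cytokine genes peaked on day 1, macrophage genes on day 3 and cell cycle genes on day 5, matrix genes stayed above 2.0 from day 3, and the median of oxidative phosphorylation genes was lowest on day 5.

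Regulators of muscle growth and of myogenesis changed as follows. Mstn, which encodes the growth inhibitor myostatin, fell by 1.54 ± 0.15 on day 1 and fell by 3.12 ± 0.15 on day 3 (8.69-fold, adjusted p = 7.8e-09), and stood at -1.58 ± 0.15 on day 14. Igf1, the insulin-like growth factor 1 gene, was at -0.03 ± 0.09 on day 1 (adjusted p = 0.825) and rose by 1.02 ± 0.09 on day 3 and 2.15 ± 0.09 on day 14. Fst, which encodes the myostatin antagonist follistatin, rose by 0.74 ± 0.13 on day 1 and 1.15 ± 0.13 on day 14, and Igf2 rose by 3.38 ± 0.12 on day 10. In the list of these pathways 12 of 19 genes rose on day 14 (12 adjusted over the list alone) and 3 fell, with a median of 0.81 (adjusted p = 9.0e-04, and adjusted p = 0.308 with an estimated correlation). Myog, the myogenic differentiation factor myogenin, rose by 1.15 ± 0.09 on day 1 and 3.27 ± 0.09 on day 7, and Mymk, the fusion protein myomaker, by 4.02 ± 0.10 on day 7. Myod1 rose by 1.11 ± 0.12 on day 1 and stood at 0.08 ± 0.12 on day 14 (adjusted p = 0.559). Pax7, the satellite cell factor, ranged from -0.33 ± 0.08 on day 1 to 0.53 ± 0.08 on day 10 (adjusted p = 0.0041 and 9.4e-05). In the list of satellite cells and myogenic differentiation 12 of 18 genes rose on day 10 (12 adjusted over the list alone) and 3 fell, with a median of 0.57 (adjusted p = 2.8e-04, and adjusted p = 0.23 with an estimated correlation).

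Fbxo32, which encodes the ubiquitin ligase atrogin-1, was at 0.12 ± 0.13 on day 1 (adjusted p = 0.502) and fell by 1.95 ± 0.13 on day 10. Trim63, which encodes the ubiquitin ligase MuRF1, rose by 1.55 ± 0.15 on day 1 and fell by 1.48 ± 0.15 on day 10. The list of muscle atrophy and autophagy did not pass on any day; on day 10, 9 of 15 fell (9 adjusted over the list alone) and 3 rose (adjusted p = 0.147 with camera). Of the 7 measured senescence-associated genes, 6 rose on day 10 (6 adjusted over the list alone), with a median of 0.38 (adjusted p = 0.008, and adjusted p = 0.316 with an estimated correlation). Among the members with the largest changes were Ccnd1, which encodes cyclin D1 and drives the cell cycle, at 1.98 ± 0.09 on day 3, and the lysosomal galactosidase gene Glb1 at 1.92 ± 0.11 on day 5. Lmnb1, which encodes lamin B1, rose by 1.06 ± 0.09 on day 1 and stood at 0.52 ± 0.09 on day 10. These rises do not by themselves show senescence. Cdkn2a, the cell cycle inhibitor gene that is the usual mark of senescence, did not pass on any day and lay between -0.25 ± 0.14 and -0.07 ± 0.14, though with the side as a block its day 14 value passed (adjusted p = 0.0398). Cdkn1a was matched only to probes of several genes and was not tested.

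Markers of other cell types followed different courses. Of 14 genes of dendritic cells and MHC class II 11 rose on day 5 (13 adjusted over the list alone), with a median of 1.21 (adjusted p = 2.5e-05, and adjusted p = 0.316 with an estimated correlation). H2-Ab1 and H2-Aa rose by 2.10 ± 0.15 and 2.06 ± 0.15 on day 14. Of 17 T and NK cell genes 12 rose on day 14 (12 adjusted over the list alone), with a median of 0.63 (adjusted p = 2.0e-05, and adjusted p = 0.206 with an estimated correlation). The T cell receptor gene Cd3g rose by 2.14 ± 0.17. Of 19 interferon response genes 18 rose on day 3 (19 adjusted over the list alone), with a median of 1.33 (adjusted p = 2.1e-09, and adjusted p = 0.316 with an estimated correlation). Mx1 rose by 2.47 ± 0.14. Of 13 complement genes 9 rose on day 14 (9 adjusted over the list alone), with a median of 1.19 (adjusted p = 2.2e-04, and adjusted p = 0.316 with an estimated correlation). The receptor gene C3ar1 rose by 4.02 ± 0.12 on day 3. Of 15 fibro-adipogenic progenitor genes 12 fell on day 1 (12 adjusted over the list alone, median -0.67, adjusted p = 5.4e-04, and adjusted p = 0.382 with an estimated correlation). On day 14, 13 of them rose (13 adjusted over the list alone, median 0.89, adjusted p = 4.1e-06, and adjusted p = 0.316 with an estimated correlation), with the microfibril gene Mfap5 at 2.79 ± 0.09 and the proteoglycan gene Lum at 2.39 ± 0.13. Of 14 tendon and cartilage genes 10 rose on day 14 (10 adjusted over the list alone, median 1.05, adjusted p = 1.4e-05, and adjusted p = 0.316 with an estimated correlation). Tnmd rose by 3.23 ± 0.16 and Acan by 2.76 ± 0.20. Clock genes were lower, with 14 of 15 falling on day 7 (14 adjusted over the list alone, median -0.86, adjusted p = 4.6e-05, and adjusted p = 0.316 with an estimated correlation) and Hlf at -1.49 ± 0.09.

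Over all 6 comparisons with day 0, 2000 genes were higher and 2346 lower on every day. In 20 simulated tables with no change, 0 genes were so. With no effect on any day that result was all but fixed in advance, so it does not measure what the shared day 0 arrays add. Independent lists of these sizes would share 4.45 and 15.4 genes, but the 6 comparisons share day 0 and are not independent. The 2 day 0 arrays entered all 6 comparisons and were too few to split, so part of the overlap may come from them. A moderated F test in limma found 15846 of 19938 genes (79.5%) differing over the 7 days. The median gene differed from day 0 by 0.04, -0.07, -0.12, -0.14, -0.13 and -0.11 on days 1 to 14, so small changes are to be read against that shift. The share of calls that were higher depended on the scaling. It was 49.7%, 47.5%, 43.9%, 42.3%, 43.0% and 42.9% on the 6 days as deposited. It was 45.7%, 35.9%, 30.8%, 28.8%, 29.2% and 28.4% with equal array medians, and 45.0%, 56.0%, 58.0%, 59.4%, 58.7% and 59.7% with the median difference set to 0. Of the 42 gene lists tested, 26, 26, 25, 26, 25 and 25 were shifted on the 6 days with camera at a preset correlation, and 0 on any day with an estimated correlation.

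**Figure D3:**
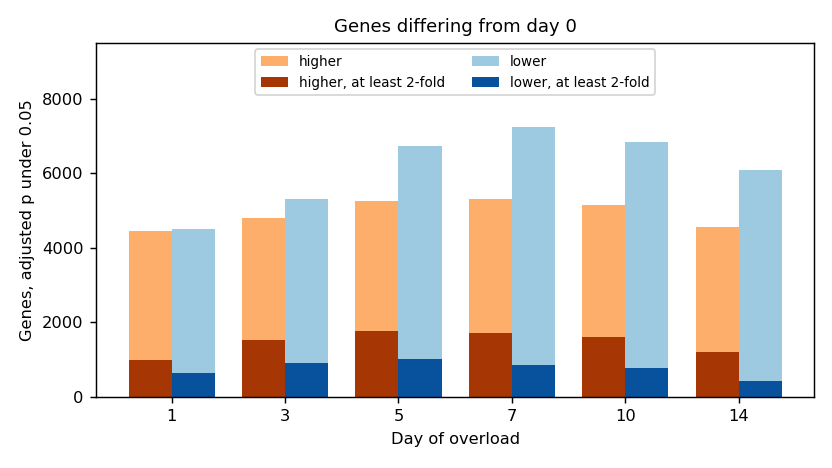
Number of genes (vertical axis) that were higher (orange) or lower (blue) than on day 0 at an adjusted p under 0.05, for each day of overload (horizontal axis); the dark part of each bar is the genes at least 2-fold apart. At least 2-fold higher genes were most numerous on day 5, with 1753, and outnumbered the at least 2-fold lower genes on all 6 days.

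Between successive sampled days the largest step after surgery was from day 1 to day 3, when 8819 genes differed, 3896 higher and 4923 lower. Gpnmb, a glycoprotein of lipid-laden macrophages, was 3.47 ± 0.17 higher on day 3 than on day 1, while Retnlg, a gene of neutrophils, stood at -2.42 ± 0.32 and Il1f9 at -2.35 ± 0.33. Between days 3 and 5, 1313 genes differed, led by Myh3 at 2.38 ± 0.16, Igf2 at 2.30 ± 0.12 and Tecrl at 2.15 ± 0.17, and with Ero1a, an oxidase of protein folding, at -1.48 ± 0.12 and Derl3 at -1.34 ± 0.10. Between days 5 and 7, 205 genes differed, with the growth factor gene Ptn at 1.28 ± 0.10 and Cxcl2 at -1.74 ± 0.28, a call that ended without any one of the 4 arrays. Between days 7 and 10, 386 differed, with Dlk1, an imprinted gene of a membrane protein, at 1.32 ± 0.14 and Arg1 at -1.47 ± 0.15, a call that ended without the right pool of day 10. Between days 10 and 14, 1775 differed, with the chemokine gene Cxcl13 at 1.48 ± 0.20, Hmox1 at -1.71 ± 0.13 and the gelatinase gene Mmp9 at -2.10 ± 0.23. The counts of the last 4 steps were unstable. Each fell by over 1.5 times when single arrays of the days compared were left out. The count between days 7 and 10 also fell so without either pool of day 3 or of day 5. Leaving out 1 array leaves 1 for its day, so a deviating array and lost replication cannot be told apart.

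Between right and left muscles, with the day as a block, limma called 0 genes. At an unadjusted p under 0.05 there were 2092 genes, where 997 are expected by chance, and with an intensity trend and robust estimation limma called 5. Without either array of day 0 it called 2. The smallest adjusted p was 0.282. The genes with the smallest p were Tspan8, Igfbp6 and Adamts9, at -0.28, -0.30 and -0.23 on the log2 scale, right minus left; they were chosen after their values were seen.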

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

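The tests of the time of day, of marrow or blood and of the number of neutrophils were chosen only after the results were seen, as was the form of the fibre comparisons that takes the differences gene by gene. For the clock genes that added form changed the reading of a planned test, which on its own terms left a lower share of fibre RNA as sufficient. With 2 arrays per day, no array can be judged to lie far from its group. What follows first are differences between the effects of successive days.

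The effect against day 0 differed between days 3 and 1 for 8819 genes, by limma's test of the difference. Between days 5 and 3 it differed for 1313 genes. Between days 7 and 5 it differed for 205 genes, between days 10 and 7 for 386 and between days 14 and 10 for 1775. The last 4 counts were unstable, and each fell by over 1.5 times when single arrays of the days compared were left out. Leaving out 1 array leaves 1 for its day, so a deviating array and lost replication cannot be told apart.

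Oxidative phosphorylation genes fell on day 5, with a median of -1.06. A lower share of muscle fibre RNA may account for this: 25 genes written down as made only by fibres, of the same level range, had a median of -1.10. All 30 measured genes of that set had a median of -0.89, a smaller fall. The median of oxidative phosphorylation genes minus that of the fibre genes, taken within each array and then day 5 minus day 0, was 0.206 ± 0.065, and 0.048 ± 0.087 in the form taken gene by gene. Compression of bright genes at the top of the range stays open, with Spearman's rho 0.248 across fibre genes between level and change (permutation p = 0.184; genes are not independent replicates). A change within fibres, as the design's overload could bring, was not tested.

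Clock genes were lower on days 5 to 14, with a median of -0.86 on day 7. Sampling at another hour would raise some clock genes, since they peak at different times. Of 15 clock genes, 2 rose and 8 fell on day 1, 1 rose and 11 fell on day 3, and 0 rose on days 5 to 14. The lack of rises on the later days does not exclude another hour, because a lower share of fibre RNA could hide rises. Against the median fibre gene, 6 clock genes lay higher and 2 lower on day 5, and 1 higher and 7 lower on day 14. Setting clock genes against fibre genes assumes that clock gene RNA came from fibres, which was not tested. A lower share of fibre RNA cannot be told apart, because the forms of the test differ in sign: clock minus fibre medians, day 14 minus day 0, were 0.146 ± 0.119, and -0.24 ± 0.07 gene by gene. An effect of overload on the clock stays open and was not tested.

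On day 3 all 9 granule genes of granulocyte precursors fell, with a median of -1.14. By contrast, 6 of 6 receptor genes counted as neutrophil genes rose, among them Trem1, Clec4e and Il1r2. Macrophage genes rose on that day too, so the rises of these receptor genes cannot be assigned to neutrophils. On day 1, 4 granule genes fell, and on day 14, 1 receptor gene rose and 1 fell. Both gene sets were chosen after the data were seen, so these counts describe the pattern and are no independent evidence for it. On day 1 all 13 measured neutrophil genes of the list other than granule genes rose, with a median of 2.04. That argues against fewer neutrophils on day 1 only if neither RNA per cell nor expression in other cells rose, which was not measured. Fewer neutrophils stays open later, when these genes went both ways: 7 rose and 1 fell on day 3, 6 rose and 6 fell on day 10 with a median of -0.24, and 1 rose and 8 fell on day 14. Marrow or blood carried into the pools may have varied: the level of the granule list was 9.45 and 8.92 on the left and right arrays of day 0 and between 7.25 and 8.29 on the others. The right minus left difference of granule genes went with that of B cell genes at Pearson's r = 0.527 over 7 days (exact permutation p = 0.224, Spearman's rho = 0.679, exact permutation p = 0.110, 1 relation computed), which decides nothing. Leaving out days 10 and 5, the farthest from the median granule difference, gave r = 0.925, which is no evidence for the relation since these days also lay off it; overload itself was not tested.

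For right against left, limma called 0 genes with 2092 at an unadjusted p under 0.05, and 5 with an intensity trend and robust estimation. With 0 genes called, all 64 flips of sides within days give at least as many by construction, and the highest of the other flips gave 1, so the flips add no evidence.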

How the results depend on the processing

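The shift that sets the median difference to 0 was chosen after the data were seen. Of 391 named gene comparisons, 355 were called, and 330 of these calls held under every alternative in which named genes were tested again. Named genes were not tested again under the stricter thresholds, over all probe sets or without the marrow and related genes. Of 153 called list and day tests, 121 held under all alternatives run for lists but the estimated correlation. Under that correlation 0 lists were called on each of the 6 days. Besides it, lists were tested again with quantile normalization, equal array medians, the lowest 25% of genes left out, the side as a block, fry and each array left out. With equal array medians 9288 genes were lower on day 14. With the median difference set to 0, 4466, 4374, 4314 and 3720 genes were lower on days 5, 7, 10 and 14; lists were not tested again under that shift. Without the lowest 25% of genes, 329 differed between days 7 and 5 and 628 between days 10 and 7; with trend and robust estimation 362 and 669, and 5 between sides; with array weights 388 and 737; with only the 4 arrays compared 95 and 151. Over all probe sets 7977, 8107 and 7956 were higher on days 5, 7 and 10, and 20, 67 and 1020 differed over the last 3 steps. At an adjusted p under 0.01, 3843 were lower on day 14 and 5394, 595, 34, 43 and 485 differed over the 5 steps. At least 2-fold, 980, 1513, 1753, 1709, 1614 and 1209 were higher and 630, 900, 1009, 846, 781 and 430 lower on the 6 days, and 838, 84, 25, 14 and 69 differed over the steps, since fewer genes pass a stricter rule. For the others the cause was not tested. With the side as a block no count moved by over 1.5 times (205 became 249 between days 7 and 5), but 3 list calls were lost (B and plasma cells and Hypoxia response on day 3, Adipocytes on day 10), 3 were gained (Fibro-adipogenic progenitors on day 5, Stretch and sarcomere stress on day 7, Endothelial cells on day 14), and Cdkn2a on day 14 and Fst on day 3 became calls. Under fry, Complement (-0.28) and Developmental contractile genes (-0.10) on day 1 had the other sign. Leaving out each array, with the lone array of a day assumed to vary like the others, genes lower on day 14 ranged from 4028 to 6192. Differences ranged from 525 to 1391 between days 5 and 3, 13 to 291 between days 7 and 5, 1 to 459 between days 10 and 7, 237 to 1948 between days 14 and 10 and 0 to 2 between sides. The lowest were without the right pool of days 14, 5, 5, 10 and 10, and the 2 side genes came without either array of day 0. Signal over background was not analysed here, so faint genes carry an unknown limit.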

Other observations

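The tests of imprinted genes beyond those that prompted the list, and the list itself, were chosen only after the result was seen, as was the gene by gene form of the fibroblast test. Genes of the neuromuscular junction and denervation diverged. Chrng, the fetal acetylcholine receptor subunit, rose by 2.93 ± 0.10 on day 7, Runx1 by 2.72 ± 0.07 on day 1 and Ncam1, a neural adhesion molecule, by 2.63 ± 0.10 on day 10. In that list 6 of 13 rose and 5 fell on day 7 (6 rose adjusted over the list alone), and the list did not pass on any day (day 7, adjusted p = 0.161 with camera). Of 12 cholesterol synthesis genes 9 rose on day 7 (9 adjusted over the list alone, median 0.43, adjusted p = 0.0318, and adjusted p = 0.461 with an estimated correlation), a call that ended without the right pool of day 7, with quantile normalization and without the 25% of genes with the lowest signal. Sqle, the squalene epoxidase, and Srebf2, the regulator of the pathway, rose by 1.45 ± 0.14 and 1.03 ± 0.08 on day 7.

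Of 11 Schwann cell genes 6 fell and 3 rose on day 10 (7 fell adjusted over the list alone, adjusted p = 0.614 with camera), with Mbp, the myelin basic protein, at -0.79 ± 0.11 and Egr2 at 1.75 ± 0.14 on day 5. Of 10 mast cell genes 3 rose and 1 fell on day 14 (3 rose adjusted over the list alone, adjusted p = 0.441 with camera), Cpa3 by 1.00 ± 0.21. Of 11 B and plasma cell genes 7 fell on day 3 (8 adjusted over the list alone, median -0.39, adjusted p = 0.04995 with camera, and adjusted p = 0.537 with an estimated correlation). That call ended with the side as a block and, among other alternatives, without the left pool of day 0. All 9 granule genes of granulocyte precursors, a list chosen after the data were seen, fell on the same day, with a median of -1.14. Marrow or blood carried into the pools stays open for both: the level of the granule list was 9.45 and 8.92 on the arrays of day 0 and between 7.25 and 8.29 on the others. Ms4a1 stood at -0.91 ± 0.19 on day 7. Of 9 keratinocyte genes 5 rose on day 14 (5 adjusted over the list alone, median 0.31, adjusted p = 0.0442, and adjusted p = 0.339 with an estimated correlation), a call that ended without either array of day 0 or the left pool of day 14. The signal of Krt5, a keratin of the skin, was 9.10 on the left and 8.04 on the right array of day 14. The 4 measured red blood cell genes were not tested as a list; Bpgm fell by 1.81 ± 0.13 on day 10.

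Imprinted genes, expressed from 1 parental copy, were among the largest rises, and a hypothesis was that the class rose on day 10. Of 42 measured imprinted genes 20 rose and 7 fell, with a median of 0.18 (adjusted p = 1.4e-04 with camera and adjusted p = 0.182 with an estimated correlation), a list chosen on these data. The 10 genes that prompted it had a median of 2.97, and the other 32 had a median of 0.04, at percentile 96.0 of 10000 lists matched on level, which met the test set for a rise of the prompting genes alone. But 10 of the 32 rose and 7 fell, Zdbf2 rising by 3.44 and Peg10 by 2.50 (named after their values were seen) with Asb4 at -2.70. Over all 19938 genes, 5154 rose and 6842 fell on day 10, so the counts of the 32 do not by themselves show a rise of the class. Whether only the prompting genes rose is left open here, a reading changed after the result was seen. Fibroblast growth may have raised them. The imprinted median minus that of fibro-adipogenic progenitor genes, day 10 minus day 0, was 0.128 ± 0.081, which met the planned test of that explanation. The form taken gene by gene gave -0.13 ± 0.20 and met it too, since neither value lay above 0 by more than 2 standard errors. Fibroblast growth still cannot be told apart, because members went both ways and no rise of the class beyond the prompting genes was shown.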
